A study of Rattus norvegicus with 9 samples.

How the data were processed

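The libraries were prepared from 1 µg of total RNA with an Illumina TruSeq RNA kit, per the labels' protocols. Whether counting used strand is not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart. The submitters' processing notes name Bowtie 0.12.2 and the mouse builds mm8 and mm9, while the samples are rat and the gene identifiers are rat Ensembl genes. The aligner, rat build, annotation and counter behind the tables are therefore not given in the sources used here, and no coordinates are printed. The authors deposited 3 full tables, 1 per pair of groups, of 22050 genes each, and 3 short tables that were checked to be the genes with an FDR under 0.05 and a log2 change over 1 in either direction. Each of the 18 library columns stands in 2 full tables and was identical in both.

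The count columns hold whole numbers per gene, not normalized, per the file headers and the values. The FPKM columns, also deposited, are counts scaled by gene length and by the column's total. For genes with a count of at least 500, the length implied by count and FPKM was the same within 1% in all libraries for 3799 of 4716 genes (80.6%), and 130 were off by over 10%. The log2 fold column that the authors deposited is the log2 ratio of the group means of FPKM, with a small value in place of 0. The p-value and FDR columns were computed by the authors with a test that is not given in the sources used here; they are quoted only as the authors' deposited results. Libraries were matched to groups by the column names and the sample titles, with 9 libraries, 3 per group. Where several identifiers shared a symbol (102 symbols, 214 identifiers), each identifier was tested on its own.

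The counts as deposited were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10 in 3 libraries, minimum total 15), which left 13693 of the 17332 genes with a read, and 4718 genes had no read. Libraries were scaled by TMM (factors 0.943 to 0.968 in controls, 1.001 to 1.033 in the others). All 9 libraries entered 1 robust quasi-likelihood fit with 3 group means, 6 residual degrees of freedom and a common biological coefficient of variation of 10.3%, from which the 3 contrasts were taken. P-values were adjusted by Benjamini-Hochberg over the tested genes of a comparison, with a threshold of 0.05. Log2 changes use a prior count of 0.125, and their standard errors come from the quasi-likelihood F statistic. FPKM values are means ± SD of the 3 libraries. Principal components and correlations used log2 CPM with a prior count of 2.

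Totals ran from 14285914 to 25048521 counts. A gene at 0 reads could still be present at up to 3 counts in a library, which is 0.12 to 0.21 CPM, and folds against a group at 0 were computed against that floor per library. Such floors and intervals cover counting error only. Recovery was checked on data simulated from a single mean per gene over all libraries, with 65 to 67 genes changed at each size. Each gene was drawn on its own. The fit for OGD against control (13563 genes) recovered 39.4%, 86.4% and 97% of genes changed by a log2 of 0.5, 1 and 2. Of its 157 calls, 10 were unchanged genes. For Wnt3a plus Rspondin 1 against OGD (13552 genes) it recovered 38.8%, 76.9% and 98.5%, and 11 of 151 calls were unchanged genes. For Wnt3a plus Rspondin 1 with OGD against control (13555 genes) it recovered 47.8%, 85.1% and 98.5%, with 10 of 164. Far fewer genes were changed here than differed between OGD and control in the real data, so these rates may not hold there.

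The 29 gene lists, the tests of the report, the rule for named genes and the alternatives were fixed before the data were examined; what was chosen later is named where it is reported. The 29 lists cover hypoxia, glycolysis, the respiratory chain, the mitochondrial genome, stress, heat shock, NRF2, immediate early genes, Wnt targets and pathway, synapse, GABA, ion channels, cholesterol, inflammation, interferon, cell cycle, extracellular matrix and the markers of 9 cell types; 1 list and some of the genes that the naming rule gives are not reported here. Symbols were matched exactly, ignoring case, and Znrf3 among the Wnt targets was not matched. Lists were tested with camera (limma 3.58.1, preset correlation 0.01) on the same counts, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. KEGG pathways of 10 to 500 tested genes, from the annotation in the tables, were tested by a one-sided Fisher's exact test against tested genes that carry any pathway. The named genes were the 5 largest rises and 5 largest falls per comparison among genes past the threshold whose libraries separated, with a group mean of at least 1 FPKM and a symbol that is not a placeholder; up to 3 members of each list with the smallest adjusted p (at most 1 where fewer than 3 passed); 17 genes of Wnt signalling, hypoxia and stress named in advance; and all genes of a comparison with 30 or fewer. Apcdd1, Cenpf, Birc5, Ccna2 and single members that went against their list were named after their values were seen.

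Because the comparisons share libraries, relations between them were set beside 50 negative binomial simulations with the fitted dispersions, once with no effect and once with the OGD effect alone. Genes were drawn independently of each other, and the genes called for OGD were kept from the real data. The alternatives were DESeq2 1.42.0, RLE size factors, library totals, no filter beyond 1 read, a mean of at least 5 FPKM in a group, the replicate number as a block, each library left out in turn, limma on log2(FPKM + 1) and log2(FPKM + 0.1), only the 6 libraries compared, an added fold limit, an estimated correlation, and another background for the pathways. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9, with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.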

Results

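RNA sequencing was run on primary neurons from the cortex of Sprague Dawley rats at embryonic day 19. The 9 libraries fell into 3 groups of 3. Control cultures were left untreated. The second group went through oxygen-glucose deprivation (OGD), a culture model of the loss of blood supply in stroke. These cells were held without glucose at 1% oxygen for 4.5 h and then returned to normal oxygen. The last group also went through OGD and received Wnt3a at 100 ng/ml together with Rspondin 1 at 50 ng/ml for 24 h. Wnt3a is a secreted ligand that activates Wnt/beta-catenin signalling, and Rspondin 1 is a secreted protein that strengthens the response of cells to Wnt ligands. The hours and the oxygen level are stated only for OGD alone. The time of harvest after OGD is not given in the sources used here, and the deposited tables call the group with OGD alone vehicle, while its labels name no vehicle. In addition, cultures given the proteins without OGD were not analysed here. The stated purpose was to find the genes regulated by Wnt3a plus Rspondin 1 in neurons under OGD. The total counts were 20100579, 15605802 and 25048521 in control replicates 1 to 3, 14285914, 22261384 and 15755600 in OGD, and 19972580, 17016738 and 16510794 in OGD with Wnt3a plus Rspondin 1. Replicates were labelled as separate samples, but nothing states that they came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

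The control libraries stood far from the others. Over log2 CPM (counts scaled to a common total) of all tested genes, the first principal component held 84.1% of the variance and placed controls between -95.8 and -92.9 and the other 6 libraries between 38.1 and 53.1. OGD replicate 1 stood apart on the next component, which held 4.6%, at 38.8 against -13.9 to 10.5 for the rest. Pearson's r across genes was 0.9894 to 0.9905 within controls, 0.981 to 0.9877 within OGD and 0.9877 to 0.9893 within OGD with Wnt3a plus Rspondin 1. It was 0.8611 to 0.8886 between control and OGD libraries and 0.9793 to 0.9892 between the 2 OGD groups. No pair of replicates agreed within sampling noise (chi-square per degree of freedom 3.68 to 29.8). Transcripts of the mitochondrial genome took 3.24% to 4.1% of counts in controls, 2.91%, 4.97% and 4.52% in OGD replicates 1 to 3, and 4.08% to 4.73% with Wnt3a plus Rspondin 1. Ribosomal protein genes took 2.15% to 2.25% in controls and 2.96% to 3.37% in the other groups.

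**Figure D1:**
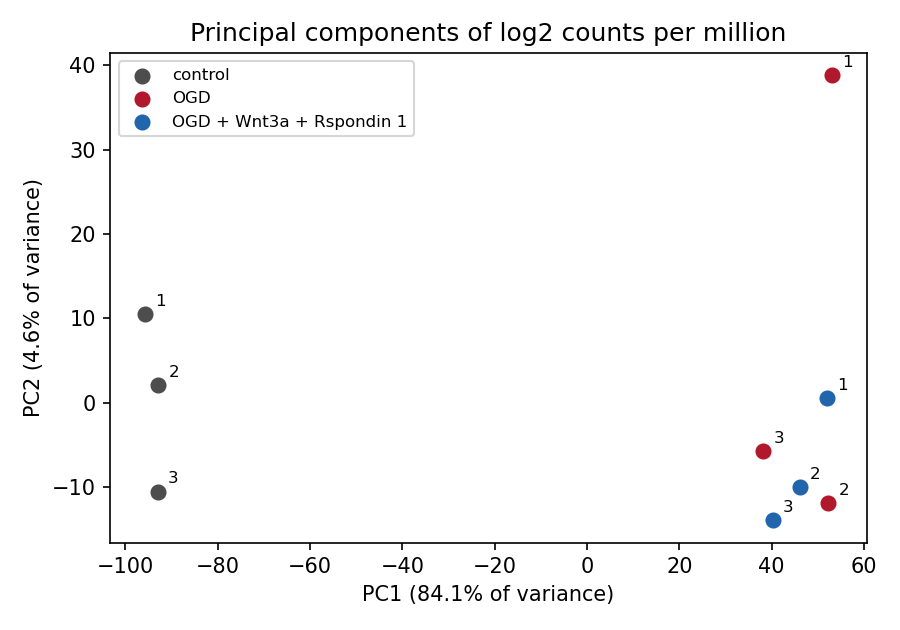
Principal components of log2 CPM, with the first component (84.1% of variance) on the x axis and the second (4.6%) on the y axis; each point is 1 library, numbered by replicate and coloured by group. Controls lie at the left, up to -92.9, and all OGD libraries at the right, from 38.1, and OGD replicate 1 lies at 38.8 on the y axis.

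OGD alone was set against untreated control, so the differences take in the return to normal oxygen and any other handling that controls did not get. Genes of neuronal identity fell. Tubb3, the neuronal beta tubulin, fell by 2.57 ± 0.13 on the log2 scale (change ± SE), from 1210 ± 113 to 216 ± 38.3 FPKM (mean ± SD, n = 3 per group). Rbfox3, the neuronal nuclear antigen NeuN, fell by 2.83 ± 0.16, and the RNA-binding protein gene Elavl3 fell by 2.29 ± 0.10. Markers of glia rose at the same time. Gfap, the astrocyte intermediate filament, rose by 1.89 ± 0.09, from 903 ± 62.2 to 3500 ± 255 FPKM, and the microglial complement gene C1qb rose by 2.62 ± 0.23, from 0.967 ± 0.248 to 6.24 ± 0.99 FPKM.

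The largest rises among genes chosen by the fixed rule were in Pdk4, a kinase that inhibits pyruvate dehydrogenase, and Angptl4, a secreted inhibitor of lipoprotein lipase. Pdk4 (ENSRNOG00000009565) rose by 5.15 ± 0.18 on the log2 scale to 65 ± 5.58 FPKM from 1.72 ± 0.294 (adjusted p = 3.42e-10), and Angptl4 (ENSRNOG00000007545) by 4.77 ± 0.17 to 234 ± 21.1 FPKM from 8.02 ± 1.94 (adjusted p = 3.89e-10). Rpe65 rose by 4.65 ± 0.57 and the proapoptotic BH3-only gene Bmf by 4.39 ± 0.18. Among the falls chosen by the same rule, the log2 change was -6.56 ± 0.38 for the adrenergic receptor gene Adra1d, -5.88 ± 0.36 for the cholecystokinin receptor gene Cckbr, -5.69 ± 0.41 for the GABA-A receptor subunit gene Gabrd and -5.48 ± 0.41 for Frmd7. Slc16a3, a lactate exporter, fell by 5.59 ± 0.24, from 10.5 ± 0.468 to 0.22 ± 0.0557 FPKM. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 10012 of 13693 tested genes (73.1%) passed an adjusted p of 0.05, with 4972 higher and 5040 lower. Of these, 1943 were at least 2-fold higher and 2581 at least 2-fold lower. The 3 libraries of one group lay wholly on one side of the other 3 for 75.1% of tested genes, against 10% by chance. With library totals in place of composition factors, 5526 genes were higher and 4592 lower.

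All 12 neuron markers measured fell after OGD (median log2 change -2.60), as did all 10 markers of excitatory neurons (-2.40), among them the transcription factor genes Fezf2 (-3.00 ± 0.12), Bcl11b (-2.27 ± 0.11) and Emx1 (-1.90 ± 0.10). Of 10 markers of inhibitory neurons, 8 fell and none rose (-1.89), with Npy at -3.42 ± 0.17. The 3 lists passed camera, a test of a list against the other genes, with a preset correlation of 0.01 (adjusted p = 1.36e-08, 4.04e-07 and 3.65e-05). Their adjusted p = 0.141, 0.127 and 0.0788 by camera with an estimated correlation, so the camera calls rest on the preset value. Fry asks whether a list moved on balance in one direction and does not set it against other genes. Its adjusted p was 6.15e-06, 1.61e-06 and 4.63e-07 for the 3 lists. Beside them, 10 of 11 astrocyte markers rose (median 1.22, adjusted p = 2.79e-07), with Gja1 at 2.03 ± 0.07 and Atp1b2 at 1.48 ± 0.07, while Glul fell by 0.36. Of the 14 microglia markers fixed in advance, 9 were measured, and all 9 rose (2.16, adjusted p = 0.00931), with C1qa at 2.16 ± 0.22. Of 9 neural progenitor markers, 7 rose and 1 fell (1.32, adjusted p = 4.17e-05), with Vim at 2.73 ± 0.11, Pax6 at 1.95 ± 0.11 and Fabp7 at 1.66 ± 0.08. Of 11 oligodendrocyte lineage markers, 6 rose and 3 fell (0.84, adjusted p = 0.0391), with Cnp at 1.69 ± 0.07, Sox10 at 1.53 ± 0.10 and Olig2 at 0.84 ± 0.07. The call of this last list was lost without control replicate 3 (adjusted p = 0.0545). With an estimated correlation these 4 lists of glia and progenitors had adjusted p = 0.0788, 0.197, 0.127 and 0.387. Markers of endothelium (5 measured, 2 higher, 2 lower, adjusted p = 0.759) and of mural cells and fibroblasts (10 measured, 4 higher, 3 lower, adjusted p = 0.230) did not pass as lists. Among them Kdr rose by 2.20 ± 0.19 and Tagln by 2.87 ± 0.13, while Ramp2 fell by 1.17 ± 0.11.

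Synaptic and excitability genes fell together. All 29 measured genes of glutamate receptors and the postsynapse were lower (median log2 change -2.14), including the metabotropic receptor gene Grm3 (-3.20 ± 0.12), the NMDA receptor subunit gene Grin3a (-3.46 ± 0.13) and the scaffold gene Shank3 (-2.14 ± 0.09). All 24 genes of presynaptic release fell (-2.57), with Cplx1 at -3.03 ± 0.11, Cplx2 at -2.40 ± 0.07 and Stx1a at -3.08 ± 0.11. All 27 voltage-gated channel genes fell (-2.27), with the calcium channel genes Cacna1g at -2.79 ± 0.10 and Cacna1a at -2.84 ± 0.10, and the potassium channel gene Kcnq3 at -3.22 ± 0.15. Of 25 genes of GABA neurons and receptors, 22 fell and 1 rose (-2.63), with Gabra5 at -4.53 ± 0.15, Gad2 at -2.98 ± 0.11 and Slc32a1 at -3.15 ± 0.13; this list shares Gad2, Slc32a1, Npy and other genes with the inhibitory markers. By camera the adjusted p was 1.36e-15, 2.84e-20, 1.14e-14 and 4.83e-11. With an estimated correlation the GABA list held (adjusted p = 0.0366), and the others had adjusted p = 0.085, 0.086 and 0.122. These falls came beside the rise of astrocyte markers (median 1.22) and microglia markers (2.16).

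Genes of cholesterol synthesis and uptake fell without exception among the 22 measured (median log2 change -2.32, camera adjusted p = 2.17e-22, adjusted p = 0.0753 with an estimated correlation). Among them Insig1 fell by 2.97 ± 0.10. Antioxidant genes regulated by NRF2, with metallothioneins, rose in 15 of 16 cases (median 1.17, camera adjusted p = 2.04e-09), and this list held with an estimated correlation (adjusted p = 0.0366). The metallothionein genes Mt1 and Mt2A rose by 3.93 ± 0.12 and 3.05 ± 0.12, and Hmox1, which degrades haem, rose by 2.04 ± 0.07 from 38.6 ± 0.768 to 168 ± 6.12 FPKM. The 1 exception, named after its value was seen, was Gsr at -0.26. Beside both lists, astrocyte markers rose by a median of 1.22 and neuron markers fell by 2.60.

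Genes induced by hypoxia were mostly lower than in control, 12 lower and 3 higher of 19 measured (median log2 change -0.64, camera adjusted p = 0.0371, adjusted p = 0.132 with an estimated correlation). Vegfa, the vascular growth factor gene, fell by 2.23 ± 0.08, from 127 ± 5.63 to 28.9 ± 0.537 FPKM. Ddit4 fell by 1.45 ± 0.10 and Pdk1 by 0.97 ± 0.08, while Pfkfb3, which promotes glycolysis, rose by 1.17 ± 0.07. The glucose transporter gene Slc2a1 had a change of 0.16 ± 0.11 (adjusted p = 0.215). Of 19 glycolysis genes, 11 fell and 3 rose (median -0.34, adjusted p = 0.0391, adjusted p = 0.617 with an estimated correlation), with Ldha at -1.48 ± 0.07 and Hk2 at -2.89 ± 0.15. Of 30 nuclear genes of the respiratory chain, 20 rose and none fell (0.32, adjusted p = 0.0391, adjusted p = 0.617 with an estimated correlation), with Sdhc at 0.70 ± 0.07, Atp5po at 0.59 ± 0.08 and Atp5f1a at 0.53 ± 0.07. Of the 13 mRNAs of the mitochondrial genome, Mt-cyb alone passed, at 0.21 ± 0.09 (adjusted p = 0.0485), and the list did not (median 0.16, adjusted p = 0.576). The Mt-cyb call was lost without control replicate 1 (adjusted p = 0.142) or 2 (0.127), without OGD replicate 2 (0.194) or 3 (0.105), with RLE size factors (0.06), without the filter on low counts (0.0637) and with only the 6 libraries compared (0.0642). The glycolysis list no longer passed without OGD replicate 2 (adjusted p = 0.0674) or 3 (0.0937), nor the respiratory chain list without OGD replicate 1 (0.0606). Beside these lists the neuron markers fell by a median of 2.60, and the astrocyte and microglia markers rose by medians of 1.22 and 2.16.

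Genes of inflammation and of the interferon response rose. Of the 22 inflammation genes fixed in advance, 11 were measured, and 10 rose and 1 fell (median log2 change 1.35, camera adjusted p = 0.00528, adjusted p = 0.132 with an estimated correlation). Nfkb2 rose by 1.68 ± 0.10, Nfkbia by 1.49 ± 0.11 and the adhesion molecule gene Vcam1 by 1.33 ± 0.10, while Tnfaip3, named after its value was seen, fell by 1.41. Of 18 interferon-stimulated genes, 16 rose and none fell (1.20, adjusted p = 0.00209, adjusted p = 0.387 with an estimated correlation), with B2m at 1.26 ± 0.07 and Gbp2 at 1.6 ± 0.12. Microglia markers rose beside both lists, by a median of 2.16.

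Further lists held changes in both directions and did not pass camera. Of 24 genes of endoplasmic reticulum and integrated stress, 8 rose and 11 fell (adjusted p = 0.777), with Psat1 at 1.47 ± 0.09, Ppp1r15a at 1.23 ± 0.08, Ddit3 at -1.02 ± 0.12 and the chaperone gene Hspa5 at -0.44 ± 0.09. Of 12 heat shock genes, 6 rose and 5 fell (adjusted p = 0.144), with Hspb1 at 3.06 ± 0.14, Hspb8 at 1.94 ± 0.10 and Hsph1 at -1.64 ± 0.07. Of 18 immediate early genes, 5 rose and 10 fell (adjusted p = 0.391), with Fos at 1.93 ± 0.11 and Nr4a3 at -2.20 ± 0.13. Of 25 cell cycle genes, 15 rose and 4 fell (adjusted p = 0.0709), with Aurkb at 2.21 ± 0.08 and Ccne1 at -2.12 ± 0.13. Of 21 extracellular matrix genes, 9 rose and 8 fell (adjusted p = 0.470), with Timp1 at 2.64 ± 0.13, Mmp14 at 1.5 ± 0.08 and Sparc at 1.34 ± 0.08; the median was 0.20 and the mean -0.18. Beside these lists the astrocyte and microglia markers rose as given above. Counts adjusted over the list alone differed from these by at most 1 gene in any list.

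Wnt target genes moved both ways after OGD, 5 higher and 7 lower of 16 measured (adjusted p = 0.740 by camera). Tnfrsf19 rose by 1.87 ± 0.08, Cd44 by 1.5 ± 0.09, Rnf43 by 2.40 ± 0.19 and Lgr5 by 0.90 ± 0.24. Nkd2 fell by 3.61 ± 0.16, Nkd1 by 0.79 ± 0.19 and Ccnd1 by 0.80 ± 0.09. Axin2, a feedback gene of the pathway, had a change of -0.07 ± 0.13 (adjusted p = 0.614) and Lef1 of 0.55 ± 0.48 (adjusted p = 0.317). Of 34 genes of the Wnt pathway itself, 15 rose and 12 fell (adjusted p = 0.466), with Sfrp2 at 1.55 ± 0.08, Wls at 1.42 ± 0.08 and Tcf7l2 at 1.36 ± 0.11. For both lists the test pointed up while the mean was negative, at -0.10 for the targets and -0.41 for the pathway genes. The rat Rspo1 gene had 33, 20 and 35 reads in controls and 0 in each OGD library, at least 8.07-fold lower against a floor of 3 counts per library, which covers counting error only. Wnt3a had 1 read in 1 control library, and Tcf7, Sp5 and Notum had too few reads to be tested.

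Among 305 KEGG pathways, 26 held more of the genes higher after OGD than the annotated genes at large, and 80 held more of the lower ones (one-sided Fisher's exact test, Benjamini-Hochberg). Higher genes made up 36 of 47 in valine, leucine and isoleucine degradation (adjusted p = 4.78e-05), 65 of 106 in lysosome (0.000587), 36 of 52 in PPAR signalling (0.00102), 26 of 35 in fatty acid degradation (0.00162) and 26 of 36 in ferroptosis (0.00318). Ribosome held 94 of 130 (1.12e-11), a pathway where reads can be split among near-identical copies and pseudogenes, so its genes are uncertain. Lower genes made up 80 of 101 in the glutamatergic synapse (2.44e-17), 59 of 74 in the GABAergic synapse (3.11e-13), 105 of 167 in axon guidance (9.68e-12) and 42 of 54 in the synaptic vesicle cycle (4.8e-09). Beside these pathways, neuron, astrocyte and microglia markers had median log2 changes of -2.60, 1.22 and 2.16.

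**Figure D2:**
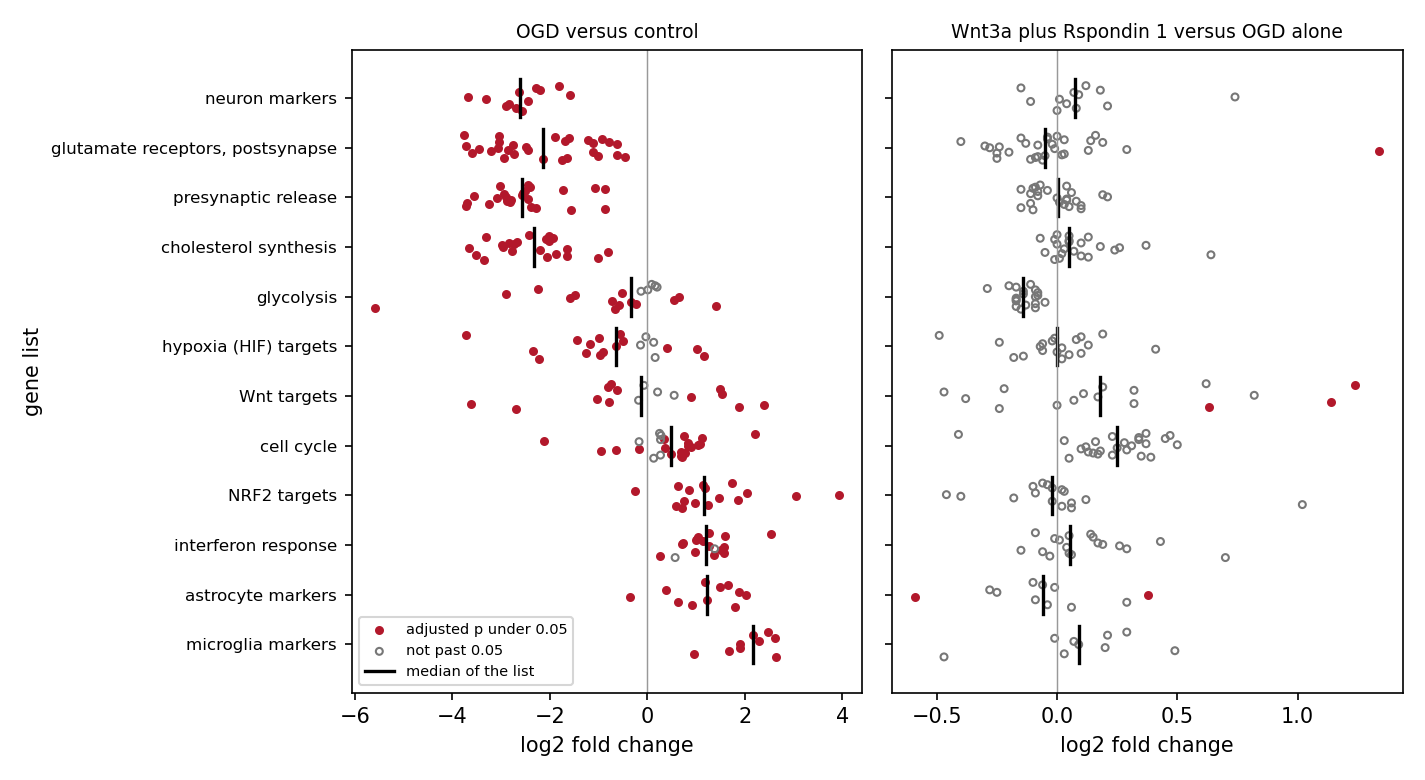
Log2 changes of the genes of 12 lists after OGD against control (left) and after Wnt3a plus Rspondin 1 against OGD alone (right, on its own x axis); each point is 1 gene, red where its adjusted p was under 0.05, and each black bar is the list's median. Neuron markers have a median of -2.60 at the left, while at the right the Wnt targets have a median of 0.18 with 3 red genes.

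The comparison of OGD with Wnt3a plus Rspondin 1 against OGD alone asks which genes the 2 proteins regulated. Axin2 (ENSRNOG00000055010), a feedback gene of Wnt signalling, rose by 1.24 ± 0.12 on the log2 scale (change ± SE), from 2.26 ± 0.245 to 5.4 ± 0.284 FPKM (mean ± SD, n = 3 per group, adjusted p = 0.000776). Nkd1 (ENSRNOG00000014293) rose by 1.14 ± 0.19, from 0.863 ± 0.107 to 1.95 ± 0.206 FPKM (adjusted p = 0.032), and the receptor gene Tnfrsf19 (ENSRNOG00000014265) by 0.63 ± 0.08, from 49.2 ± 4.2 to 71.2 ± 3.24 FPKM (adjusted p = 0.00293). The largest rise among the called genes was in Fam107a (ENSRNOG00000033261), by 2.02 ± 0.10, from 9.5 ± 1.44 to 39.3 ± 1.41 FPKM (adjusted p = 1.41e-06). Id1 (ENSRNOG00000021750), a helix-loop-helix gene induced by BMP signalling, fell by 0.82 ± 0.09, from 132 ± 12.6 to 75.7 ± 3.06 FPKM (adjusted p = 0.00109). The call of Nkd1 was lost in 5 of the 6 fits that left out 1 library (adjusted p up to 0.161).

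**Figure D3:**
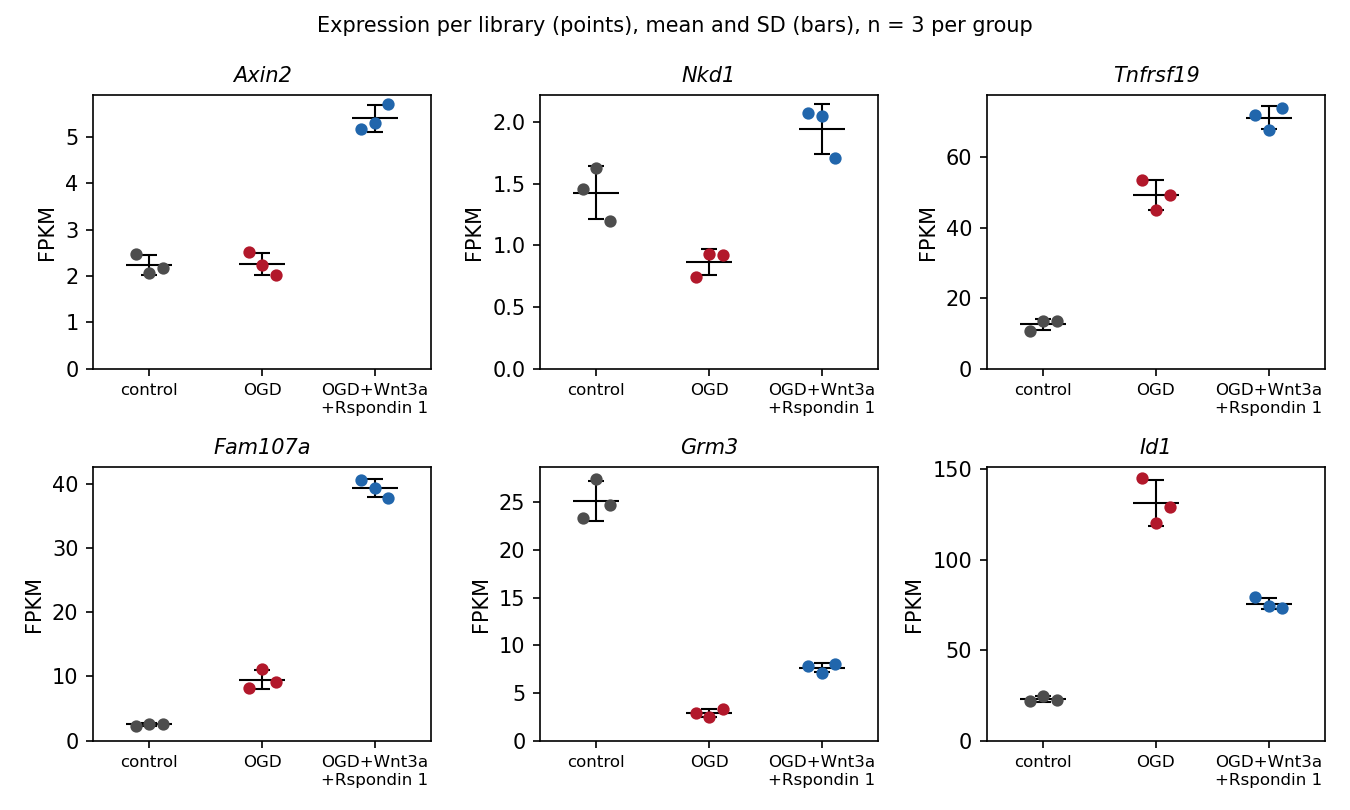
FPKM of Axin2, Nkd1, Tnfrsf19, Fam107a, Grm3 and Id1 in each library of the 3 groups, with the mean and SD of each group. Axin2 has means of 2.23, 2.26 and 5.4 FPKM in control, OGD and OGD with Wnt3a plus Rspondin 1.

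In all, 27 genes passed in this comparison by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 24 higher and 3 lower, and 12 rose at least 2-fold. DESeq2 called 101, 61 higher and 40 lower. Further genes that rose were the exchanger gene Slc24a2 (1.5 ± 0.13), Moxd1 (1.45 ± 0.23), Grm3 (1.34 ± 0.12, from 2.89 ± 0.411 to 7.64 ± 0.455 FPKM), Ildr2 (1.26 ± 0.19), the growth factor gene Pdgfc (1.22 ± 0.13), the small heat shock protein gene Hspb1 (1.04 ± 0.11), the Wnt receptor gene Fzd5 (1.02 ± 0.18), Extl1 (1.01 ± 0.11) and the endothelin receptor gene Ednra (1.01 ± 0.16). Smaller rises were in Vgf (0.84), St6galnac5 (0.84), Ptar1 (0.80), Pamr1 (0.73), Laptm4a (0.72), Chst2 (0.67), Rcan2 (0.66), Foxo1 (0.52), Atp1b1 (0.52), Cspg5 (0.46) and Gja1 (0.38). Besides Id1, the genes that fell were Glul, which makes glutamine from glutamate (-0.59 ± 0.07), and Efhd1 (-0.53 ± 0.07). OGD alone had moved 25 of the 27 away from control. For 14 of these, among them Grm3, Slc24a2, Vgf, Atp1b1 and Id1, the proteins moved expression in the direction opposite to OGD, which the shared OGD libraries favour by chance, and for 11, among them Fam107a, Tnfrsf19, Hspb1, Pdgfc and Gja1, in the same direction. An unadjusted p under 0.05 was reached by 784 genes, where 685 are due to chance, and the groups were separated in 9.6% of genes, where chance gives 10%.

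The number of genes depended on single libraries and on the tool. It was 48 without OGD replicate 1, which stood apart on the second component, 13 without OGD replicate 2, 12 without Wnt3a plus Rspondin 1 replicate 2 and 17 without its replicate 3, and 101 by DESeq2. In each of the 6 fits that left out 1 library, 11 genes stayed past the threshold. They were Fam107a, Slc24a2, Grm3, Axin2, Pdgfc, Id1, Extl1, Hspb1, Tnfrsf19, Glul and Rcan2. Nkd1, Fzd5, Foxo1, Gja1, Cspg5 and St6galnac5 were each lost in 5 of the 6. Tnfrsf19 lost its call by limma on log2(FPKM + 1) (adjusted p = 0.075) and on log2(FPKM + 0.1) (0.0936).

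As a list, the 16 measured Wnt targets were higher with Wnt3a plus Rspondin 1 than with OGD alone (median log2 change 0.18, camera adjusted p = 1.65e-08), and the list held with an estimated correlation (adjusted p = 0.024). Without OGD replicate 2 the list still passed, with a median of 0.10. Axin2, Nkd1 and Tnfrsf19 passed over all genes. Adjusted over the list alone 4 passed, the fourth being Apcdd1 (0.62, adjusted p = 0.0601 over all genes). Lef1 had a change of 0.82 ± 0.42 (adjusted p = 0.941) at 0.38 ± 0.0781 FPKM, Ccnd1 of 0.19 ± 0.09, Lgr5 of 0.17 ± 0.22 and Rnf43 of 0.00 ± 0.16. The 25 cell cycle genes were also higher as a list (median 0.25, adjusted p = 1.65e-08, adjusted p = 0.024 with an estimated correlation). None passed singly over all genes by edgeR's test, where 13 had an unadjusted p under 0.05 (12 of them higher), and 1 passed by DESeq2. Adjusted over the list alone 2 passed, 1 higher and 1 lower. Cenpf was at 0.50, Birc5 at 0.47, Ccna2 at 0.45 and Aurkb at -0.41. Both lists also moved on balance in one direction by fry, with adjusted p = 0.00811 for each. The medians of the marker lists ran from -0.20 for mural cells and fibroblasts to 0.18 for inhibitory neurons (adjusted p = 0.00205, adjusted p = 0.267 with an estimated correlation), with -0.06 for astrocytes, 0.09 for microglia and -0.02 for neural progenitors.

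No other list held with an estimated correlation. Inhibitory neuron markers (median log2 change 0.18, adjusted p = 0.00205), GABA genes (0.11, 0.0289), endoplasmic reticulum stress (0.11, 0.00164), heat shock (0.03, 0.0325), the mitochondrial genome (0.10, 0.0289) and cholesterol synthesis (0.05, 0.0453) passed camera upwards with the preset correlation. Glycolysis (-0.14, 1.45e-05), immediate early genes (-0.11, 0.0289), ion channels (-0.08, 0.0482) and extracellular matrix (-0.12, 0.0325) passed downwards. With an estimated correlation the adjusted p was between 0.267 and 0.837 for these 10 lists, and 9 of them, all but glycolysis, also lost the call when some single library was left out. The remaining lists, among them neuron markers (median 0.07), excitatory markers (0.02) and presynaptic genes, did not pass. Neuron markers passed upwards without OGD replicate 3 (adjusted p = 0.000413) and without Wnt3a plus Rspondin 1 replicate 1 (0.0038), and presynaptic genes downwards without OGD replicate 2 (0.0405) and without Wnt3a plus Rspondin 1 replicate 3 (0.023). Also newly past were the respiratory chain downwards without OGD replicate 3 (adjusted p = 0.00327) and without Wnt3a plus Rspondin 1 replicate 2 (0.00973), astrocyte markers (0.00938) and neural progenitor markers (0.0204) downwards without OGD replicate 3, and glutamate receptor and postsynaptic genes downwards and interferon genes upwards without Wnt3a plus Rspondin 1 replicate 3 (0.0401 for each). Changes in the hypoxia and stress genes named in advance were small, at 0.02 ± 0.07 for Vegfa, -0.18 ± 0.11 for Slc2a1, 0.05 ± 0.08 for Pdk1, 0.13 ± 0.09 for Hspa5 and 0.09 ± 0.13 for Ddit3, none past the threshold. No KEGG pathway was enriched among the 24 higher or the 3 lower genes by Fisher's exact test with Benjamini-Hochberg adjustment, nor with all tested genes as background. Only 16 and 2 of these genes carried a pathway, and 13 and 11 pathways had an unadjusted p under 0.05 by this exact test.

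OGD with Wnt3a plus Rspondin 1 was also set against untreated control, which shows how far the treated cultures were from cells without OGD. Pdk4, Angptl4, Slc16a3 and Adra1d were again among the genes chosen by the rule for large changes. Pdk4 rose by 4.80 ± 0.18 on the log2 scale, Angptl4 by 4.66 ± 0.17 to 221 ± 32.4 FPKM, Rpe65 by 4.56 ± 0.58 and Bmf by 4.32 ± 0.18. Falls chosen by that rule were -5.68 ± 0.24 in Slc16a3, -5.70 ± 0.46 in Col24a1, -5.30 ± 0.32 in Adra1d and -5.09 ± 0.37 in the estrogen receptor gene Esr1. Cetn3 had no read in the treated libraries and was at least 16.6-fold lower than in control against the floor of 3 counts per library. Tubb3 fell by 2.57 ± 0.13 and Gfap rose by 1.64 ± 0.09. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 9941 genes (72.6%) passed, 5018 higher and 4923 lower, with 1908 at least 2-fold higher and 2585 at least 2-fold lower. The groups were separated in 78.7% of genes, against 10% by chance. Library totals in place of composition factors gave 5669 higher and 4408 lower.

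Neuron markers (0 higher and 12 lower, median log2 change -2.57), glutamate and postsynaptic genes (0 and 29, -1.93), presynaptic genes (0 and 24, -2.55), ion channels (0 and 27, -2.41) and cholesterol synthesis (0 and 22, -2.26) fell as after OGD alone. NRF2 targets (15 higher and 1 lower, 1.14), astrocyte markers (9 and 1, 1.14), microglia markers (9 and 0, 2.17) and interferon genes (18 and 0, 1.32) rose. The highest camera adjusted p of these 9 lists was 0.00546, and with an estimated correlation no list passed, the lowest adjusted p = 0.0759 being that of the NRF2 list. The cell cycle list rose here, with 19 higher and 3 lower of 25 (median 0.80, adjusted p = 0.00744, adjusted p = 0.116 with an estimated correlation). Of 16 Wnt targets, 7 rose and 4 fell (adjusted p = 0.252). Axin2 rose by 1.16 (adjusted p = 1.73e-06), Tnfrsf19 by 2.5 ± 0.08, Lef1 by 1.37 (adjusted p = 0.0129, or 0.0555 without control replicate 3) and Kremen1 by 1.64 ± 0.11, Nkd2 fell by 3.29 ± 0.16, and Nkd1 had a change of 0.35 (adjusted p = 0.0969). Nkd1 passed with library totals (adjusted p = 0.0346) and by limma on log2(FPKM + 1) (0.0233) and log2(FPKM + 0.1) (0.0475). Vegfa fell by 2.21 ± 0.08 and Slc2a1 had a change of -0.03 (adjusted p = 0.836). Of KEGG pathways, 25 were enriched among higher genes and 90 among lower ones. Rspo1 had 2, 1 and 2 reads, and its control to treated ratio was 15.5 (95% counting interval 6.4 to 48.9).

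The 2 comparisons against control shared their control libraries, and the changes correlated across genes at Pearson's r = 0.979. Simulated groups without any change gave 0.489, and groups with the OGD effect alone 0.984. The covariance was 1.41 against 0.0227 without any change. Of the higher genes, 4644 were shared, where independent lists would share 1822, and of the lower ones 4712, against 1812. With 3 control libraries they cannot be split with 2 on each side, so part of the excess may come from the shared controls. Genes are not independent replicates in these values.

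Whether the proteins moved genes back towards control was examined across all 13693 genes. The OGD effect and the effect of Wnt3a plus Rspondin 1 correlated at r = -0.151 (Spearman's rho -0.14), but both contain the OGD libraries. Groups simulated with the OGD effect alone gave r = -0.0924 (range -0.119 to -0.0602 over 50 simulations) and groups without any effect -0.515. Each gene was simulated on its own, so variation that genes share within a library is absent and these ranges may be too narrow. The covariance was -0.0447 against -0.0244, a difference of -0.0204. Of the 10012 genes changed by OGD, 56.2% moved the opposite way, against 50.1% (48.9% to 51.5%) in the simulation. The 10012 genes were called on the same OGD libraries, and the simulation kept them without calling genes anew. It leaves out the excess that this choice gives by chance, so its share is no test of the 56.2%. The correlation of the effects rested on single libraries. Without OGD replicate 1 it was -0.0981 and without OGD replicate 2 -0.13, both inside their simulated ranges of -0.155 to -0.0884 and -0.148 to -0.0956. Without OGD replicate 3 it was -0.311, and without Wnt3a plus Rspondin 1 replicate 3 it was -0.0504, beyond the other end of its range of -0.113 to -0.0579.

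The authors' deposited tables held 9621, 62 and 10148 genes with an FDR under 0.05 for OGD against control, for Wnt3a plus Rspondin 1 against OGD and for Wnt3a plus Rspondin 1 with OGD against control. Of these, 9377, 26 and 9590 also passed here, and 9375, 26 and 9585 of them in the same direction. With a log2 change over 1 as well, the authors' deposited table for Wnt3a plus Rspondin 1 against OGD held 15 genes, all higher.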

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

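The tests of the neuron share as the whole cause, of OGD replicate 1, of the cell mixture and of progenitors were chosen after the results were seen; those of the composition factors, of gene length and of other splits were set before. The change from control differed between OGD alone and OGD with Wnt3a plus Rspondin 1 for 27 genes by a test of the difference itself, edgeR's contrast between the 2 OGD groups. The splits of the 6 libraries of a comparison into 3 and 3 number 10 with the real one, too few for a share under 0.05, and in each comparison 1 split, the real one, reached the real value. For OGD against control the real split called 9753 genes and the highest other 0, for Wnt3a plus Rspondin 1 against OGD 15 and 4, and for OGD with Wnt3a plus Rspondin 1 against control 10438 and 0, all in fits of the 6 libraries alone.

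Neuron and synapse genes fell and glial markers rose after OGD. A lower share of neurons alone would raise genes expressed only in other cell types alike. The 6 marker lists of such types moved apart (permutation p = 0.0092 by the Kruskal-Wallis statistic over 100000 permutations of genes). Their medians were 2.16 for microglia, 1.32 for neural progenitors, 1.22 for astrocytes, 0.84 for the oligodendrocyte lineage, 0.67 for endothelium and 0.60 for mural cells. Members of single lists also spread widely, from -3.02 to 4.16 for mural cells and from -1.8 to 2.73 for neural progenitors. The test takes genes as independent, and markers that neurons also express would give such differences, so it does not decide on this cause. The composition factors fail as a cause, since the neuron markers stayed at -2.52 or lower with library totals and with RLE, and gene length as well, since their median was -2.70 after the length trend was removed and -2.60 before. What stays open is a loss of neurons alone, a loss of neurons together with a change within the glia, or a fall of transcription in surviving neurons, and bulk libraries hold no count of cells. Astrocyte marker transcripts were also present without OGD, with Gfap at 903 FPKM in controls.

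Wnt targets were higher with Wnt3a plus Rspondin 1. OGD replicate 1, which stood apart, is not the cause, since without it the median of the list was 0.17 against 0.18 (adjusted p = 4.76e-09, range over alternatives 4.76e-09 to 0.024). Over the alternatives the median ran from 0.10, without OGD replicate 2, to 0.24. Another mixture of cells stays open, since the highest median of the 9 marker lists, that of inhibitory neurons, was also 0.18, although that list had an adjusted p = 0.267 with an estimated correlation. A response of the cells to the added proteins, which the design names, stays open as well and may account for the rise.

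Cell cycle genes were higher as a list with Wnt3a plus Rspondin 1, although none passed singly by edgeR's test, where 13 had an unadjusted p under 0.05, and 1 passed by DESeq2. Without OGD replicate 1 the median stayed at 0.25 (adjusted p = 8.57e-07, range over alternatives 1.57e-08 to 0.024). The neural progenitor markers showed no rise as a list, with a median of -0.02 and an upper quartile of 0.03. Markers that astrocytes also express could hide a larger share of progenitors, so this does not decide on that cause. A larger share of progenitors or more division among other cells, such as glia, stays open. Either may be a response to the proteins, and no measure of cell number was analysed here.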

How the results depend on the processing

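For OGD against control and for OGD with Wnt3a plus Rspondin 1 against control, the counts of higher and lower genes stayed within 1.5 times under every alternative but 1, the added fold limit, which by its construction left 1943 higher and 2581 lower, and 1908 and 2585. Leaving out single libraries gave 4654 to 5095 higher and 4693 to 5052 lower, and 4654 to 4868 and 4604 to 4700. Library totals moved the median log2 change of all genes from 0.02 to 0.105 and from 0.032 to 0.138, so directions of small changes against control hold relative to that shift. Wnt3a plus Rspondin 1 against OGD alone (24 higher, 3 lower) depended more on the setting: DESeq2 gave 61 and 40, RLE 19 and 5, no filter 32 and 7, only the 6 libraries 12 and 3, the fold limit 12 and 0, and single libraries left out 10 to 37 and 2 to 11. All 27 genes were among the 101 of DESeq2, the 39 without a filter and the 48 without OGD replicate 1, and the cause of these differences was not tested. With the replicate number as a block the count was 65 (43 higher, 22 lower), with all 27 kept, and 10301 and 10229 against control. Same-numbered libraries correlated in their deviations at 0.07 to 0.27 between the OGD groups, over 0.1 in 2 of 3 pairs. The values were -0.05 to 0.27 for OGD and control and -0.07 to 0.07 for the third pairing. They do not settle whether the numbers pair the samples, which the labels do not state. Between the OGD groups each of the 6 libraries correlated best with its own number, a hint from the data, not the design. The background of all tested genes gave 39 enriched pathways among higher genes of OGD with Wnt3a plus Rspondin 1 against control in place of 25. The relation of the treatment effect to the OGD effect (-0.151) ran from -0.311 to -0.0504 with single libraries left out. It went to the other side of its simulated mean without OGD replicate 1 (-0.0981) and without Wnt3a plus Rspondin 1 replicate 3 (-0.0504). Over the OGD genes alone it was -0.182. With the block it stayed at -0.151 by construction, since each number stands once in each group, so the block is no check of it. The side was judged against the simulated mean of each setting, a rule set after these values were seen. The cause was not tested. Of the list results past the threshold, 2 turned direction, both between the OGD groups, the mitochondrial genome without OGD replicate 1 (-0.09, adjusted p = 0.479) and ion channels without OGD replicate 3 (0.02, adjusted p = 0.807), with ranges of -0.09 to 0.28 and -0.22 to 0.02 over the libraries left out. Medians of lists not past the threshold took another sign, or went to or from 0, in 11, 45 and 6 values of the 3 comparisons. An estimated correlation ended 17, 10 and 19 list calls in the 3 comparisons, and other settings ended 5, 22 and 0 and brought 0, 11 and 3 values newly past the threshold, 1 of them with the block, for astrocyte markers (adjusted p = 0.0317). Of the values of named genes, 18 of 1634, 95 of 583 and 17 of 1664 were no longer past the threshold. None turned direction after passing. The totals include genes that the main fit had not called, which cannot lose a call. Between the OGD groups, 27 of the 37 named genes were called, and all 95 lost values fell on these 27. Depth limits genes near the floor, such as Lef1, Rspo1 and Wnt3a.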

Other observations

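The test of PPAR targets was chosen after the KEGG result was seen; that of BMP targets was set before its result, after Id1, Id2 and Id3 had been seen and left out of the list. Single genes with reads in some libraries only stood out. Cetn3 had 73, 31 and 71 reads in controls, 0, 0 and 30 in OGD and none with Wnt3a plus Rspondin 1. Ceacam4, in the authors' deposited table the largest rise with Wnt3a plus Rspondin 1, had 0, 0 and 8 reads in controls, none in OGD alone and 16, 39 and 17 with the proteins, at least 7.7-fold higher than OGD alone against the floor of 3 counts per library.

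Fatty acid genes rose after OGD. Besides Pdk4 and Angptl4, 18 other PPAR targets of fatty acid use were measured, and 17 were higher and 1 lower (median log2 change 1.28). Cpt2 was at 2.22, Decr1 at 2.14, Cpt1a, which brings fatty acids into mitochondria, at 2.06 and Acadvl at 1.88, while Fabp3 was at -0.72. Fry gave p = 2.75e-09, camera 4.09e-12 and 0.000743 with an estimated correlation. Higher PPAR activity is a candidate explanation, and so is a change in the share or state of astrocytes, which use fatty acids and whose markers rose beside it (median 1.22), and these tests do not separate them.

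Id1 fell with Wnt3a plus Rspondin 1, and lower BMP signalling was tested as a hypothesis on 11 other measured BMP targets. Their median log2 change was -0.33 and none passed singly by edgeR's test, where 4 had an unadjusted p under 0.05, all lower, and 1 passed by DESeq2. Fry gave p = 0.0277 and camera with an estimated correlation p = 0.041, which is consistent with the hypothesis. The PPAR targets, which the hypothesis does not concern, passed both tests as well in this comparison (median -0.06, fry p = 0.0203, camera p = 0.0421 with an estimated correlation), so passing does not set the BMP targets apart. With single libraries left out, fry's adjusted p over the 2 lists of this part ran from 0.00885 to 0.0819 and was under 0.05 in 1 of 6 fits, with medians from -0.33 to -0.13, so the result rests on single libraries and may not hold. That adjustment was added after the unadjusted values were seen. After OGD alone the same list was higher than in control (median 1.62, 8 higher and 2 lower).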
